A study of Arabidopsis thaliana with 6 samples.

How the data were processed

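Aerial parts of Arabidopsis seedlings were harvested from 10-day-old plants, kept at 16 h light and 8 h dark and collected 2 h after lights on, per the labels' protocols. Total RNA was labelled and hybridised to 1 ATH1 array per sample, per the labels. 6 arrays fell into 2 groups of 3 by the genotype in the labels, wild type and SPT4-R3, and the replicate numbers are those of the sample titles. The labels call the samples biological replicates but do not say whether they came from separate sowings, so p-values measure only the spread between these samples. The deposited values are 1 number per probe set and array. They were read as log2 signals, as their range and spread show, and the submitters' processing notes name Affymetrix Expression Console as the software. The algorithm, the background correction and the normalization are not given in the sources used here, and no scan date or batch was used. Arrays carry no counts, so the number of arrays limits the precision, and no detection call was used, which leaves signals near that of the trp control (3.62 in wild type and 3.61 in SPT4-R3) open to background.

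The table held 22810 probe sets, of which 64 were array controls and 22746 were tested. In the annotation table used here 13513 of these had 1 gene, 503 had several and 8730 had none, and the last 2 kinds entered the counts of probe sets but were named for no gene. Symbols were updated through the Entrez identifier in a RefSeq gene table (assembly TAIR10.1), which held 13436 of the 13513, and the others kept the name of the annotation table. No coordinates were used except the order of genes along the chromosomes, for which 47 genes missed by the identifier were placed by locus. A gene with several probe sets was represented by the one with the highest mean over the 6 arrays. Of 146 such genes, 1 had probe sets called in opposite directions. Only 1557 of the 13356 genes carried a symbol other than their locus.

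Probe sets were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust) on the deposited values without further normalization or filter. Tests were two-sided, with the Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. SEs are those of the moderated fit. 31 gene lists with 539 entries were written before the data were examined, and 57 entries had a single-gene probe set, which reduced every list. The loss was not even, since 13513 of the 22746 probe sets had 1 gene. The measured members, and the genes they were compared with, may therefore not represent the full lists or all genes. The 5 lists with at least 4 measured genes were tested with camera on the moderated statistics, with a preset correlation between genes of 0.01 and adjustment over the 5 lists. With an estimated correlation no list or family passed. That run applied camera to the array values in place of the moderated statistics, so more than the correlation differed from the main test. The estimates were 0.0542 for Aux/IAA, -0.0661 for GH3 and SAUR and -0.0900 for cold and drought. A larger correlation therefore does not account for the higher p-values of lists with a negative estimate. As an alternative, fry asks whether a list moves one way on balance without comparing it with other genes. After the annotation had been seen, 47 families of at least 5 genes sharing the letters before the first digit of their symbol were formed and tested the same way.

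The genes named were set by a rule written before the data were examined. It took SPT4-1, SPT4-2, SPT5-1 and SPT5-2, the 12 named genes with the largest increases and the 12 with the largest decreases among those past the threshold whose genotypes did not overlap, and for each list up to 4 members with the smallest p among those past the threshold, or 2 where none passed. Members of the added families, and list members given only with their level in a caption or as exceptions, were chosen after their values were seen. Array controls were compared with exact permutation tests over the 6 arrays, two-sided.

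On simulated arrays with the spread of these data, 22746 probe sets and 200 changed ones, the fit found 10 of 50 changes of 0.25 log2, 46 of 50 changes of 0.5, 50 of 50 changes of 1 and 50 of 50 changes of 2, with 6 false calls. The list test on 13356 simulated genes called a list shifted down by 0.25 and did not call an unshifted list. The simulated genes were independent and few of them changed, while 49.9% of the probe sets were called in the data. This check therefore does not show how small a list shift can be detected here. Alternatives were quantile normalization, centring on the array median, removal of the dimmest 30% of probe sets, limma with trend and robust settings, the replicate number as a block, each array left out in turn, a test against 0.5 log2 (treat), removal of probe sets with identifiers that mark shared probes, and the mean of a gene's probe sets. Scaling on array controls was added after the data were seen. The spread of the scaling factors between arrays of a genotype enters the residual spread and so those p-values. It is common to all probe sets, and limma then gave every probe set the same SE.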

Results

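Transcript levels were measured on single-colour ATH1 oligonucleotide arrays in the aerial parts of 10-day-old Arabidopsis thaliana seedlings. 3 arrays came from wild-type plants of the accession Col-0 and 3 from SPT4-R3, a line in which SPT4 is targeted by RNA interference. SPT4 pairs with SPT5 in a conserved factor that binds RNA polymerase II during transcript elongation. The labels call the 3 samples of each genotype biological replicates. On the deposited log2 scale the array medians were 6.50, 6.54 and 6.51 in wild type and 6.53, 6.54 and 6.53 in SPT4-R3. Across 22746 plant probe sets, arrays of the same genotype correlated at 0.998 to 0.999 and arrays of different genotypes at 0.976 to 0.977. The median SD of a probe set over 3 arrays was 0.0751 in wild type and 0.0643 in SPT4-R3.

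The RNAi target was examined first. SPT4-1 (AT5G08565), the member of the SPT4 pair with a probe set of its own in the annotation used here, read 5.79, 6.05 and 6.03 on the wild-type arrays and 5.0, 4.89 and 4.97 on the SPT4-R3 arrays. Its signal fell by 1.0 ± 0.0753 (SE, n = 3 per genotype) on the log2 scale, a 2.00-fold reduction, with an adjusted p of 2.15e-06. SPT5-1 (AT2G34210), a gene of the SPT5 partner, read 3.90 ± 0.0231 (SD, n = 3) in wild type and 3.92 ± 0.0208 in SPT4-R3, close to the 3.62 of the trp control probe sets. The difference for SPT5-1 was 0.02 ± 0.0497 (SE) with an adjusted p of 0.771. SPT4-2 and SPT5-2 were not analysed here because no single-gene probe set carried their names in the annotation used. Where the probes of SPT4-1 lie relative to the RNAi fragment is not given in the sources used here.

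Changes in the SPT4-R3 seedlings were widespread and went both ways. Of the 22746 probe sets, 6007 were higher and 5344 lower in SPT4-R3, which is 49.9% of those tested. Most of these changes were small, with a median absolute difference of 0.41 on the log2 scale among the probe sets called. Differences of at least 1 on the log2 scale were found for 500 higher and 664 lower probe sets, 5.12% of those tested. Among 13356 genes represented by a single-gene probe set, 3296 were higher and 2884 lower, with 240 and 307 of them changed by at least 1. For 51.7% of the genes the 3 values of 1 genotype lay beyond all 3 of the other, against 10% by chance for 3 arrays against 3.

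The direction counts depended on the scaling of the arrays. The bacterial bioB, bioC and bioD controls, which the standard protocol adds in a fixed amount at hybridisation, were lower on the SPT4-R3 arrays. Their 14 probe sets averaged 9.01 ± 0.0302 (SD, n = 3) in wild type and 8.62 ± 0.114 in SPT4-R3, a difference of -0.39 (exact permutation test, two-sided p = 0.1, the smallest that 3 arrays against 3 allow). The poly-A controls dap, lys, phe and thr, which it adds to the RNA before labelling, differed by -0.15 (exact p = 0.2). The wild-type arrays were spread from 6.65 to 6.95 (SD 0.152) and overlapped the 6.62 to 6.68 of SPT4-R3, so this difference depends much on single arrays. The cre control, a hybridisation control like bioB, bioC and bioD, differed by -0.05 with overlapping values (exact p = 0.7). Among the control probe sets for plant transcripts, GAPDH was higher by 0.53 and actin by 0.07, and ubiquitin differed by -0.30, each with no overlap between genotypes (exact p = 0.1); centring on bioB, bioC and bioD would turn ubiquitin. The 3' minus 5' difference of the control transcripts, a sign of RNA quality, was 0.44 ± 0.0954 (SD, n = 3) in wild type and 0.63 ± 0.0721 in SPT4-R3 for GAPDH, 0.28 ± 0.0839 and 0.12 ± 0.0709 for ubiquitin, and 1.93 ± 0.168 and 2.06 ± 0.203 for actin. These ratios separated the genotypes for GAPDH and, in the opposite direction, for ubiquitin (exact p = 0.1 each), but not for actin (exact p = 0.5). In an alternative chosen after the data were seen, centring each array on bioB, bioC and bioD moved the median difference of all probe sets to 0.39 and gave 17406 higher and 1589 lower probe sets, so that 91.6% of the calls were higher in place of 52.9%. Centring on the poly-A controls moved the median to 0.15 and gave 6926 higher and 2478 lower, or 73.6% higher. All directions that follow are on the deposited scale, on which the median difference was -0.003, and so are relative to the bulk of the probe sets.

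**Figure D1:**
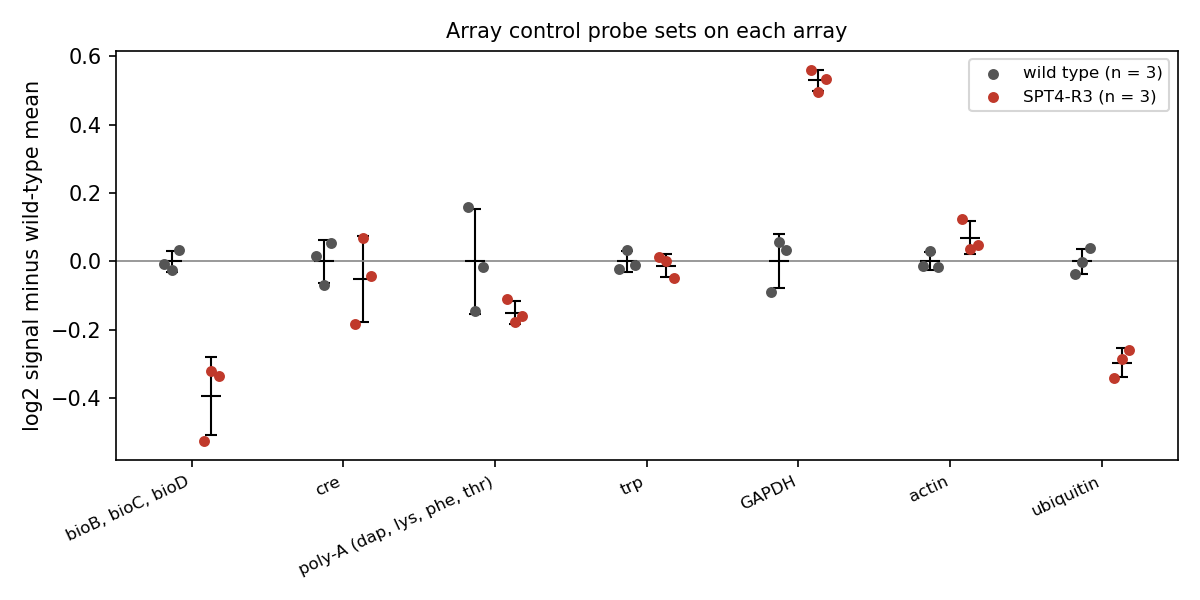
Mean log2 signal of each class of array control probe sets on each array, minus the wild-type mean of that class, with genotype means and SDs (n = 3 arrays per genotype). The bioB, bioC and bioD controls lie lower on all 3 SPT4-R3 arrays by 0.39 on average, and the GAPDH probe sets lie higher by 0.53; scaling on bioB, bioC and bioD would raise the SPT4-R3 points by 0.39 on average.

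The largest falls among named genes included an Aux/IAA gene, a homeodomain gene and an expansin gene. The 12 named genes with the largest decreases fell by between 3.04 (8.22-fold) and 5.30 (39.4-fold) on the log2 scale. IAA29 (AT4G32280), an Aux/IAA repressor of auxin response, went from 9.59 ± 0.01 (SD, n = 3) to 4.97 ± 0.07, a 24.6-fold fall (adjusted p = 3.11e-11). HAT2 (AT5G47370), a homeodomain-leucine zipper transcription factor, went from 10.76 to 7.36 and EXPA8 (AT2G40610), an expansin that loosens cell walls, from 10.76 to 7.44, falls of 10.6-fold and 9.99-fold. MSRB6 (AT4G04840), a methionine sulfoxide reductase, fell 11.1-fold, SIS (AT5G02020) 8.40-fold and ECS1 (AT1G31580) 8.22-fold. The others in this set are known here by locus. AT1G67865 fell by 5.30, AT5G62280 by 4.84, AT5G12050 by 4.40, AT1G13650 by 4.36, AT1G67860 by 4.17 and AT1G33811 by 3.37.

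The 12 named genes with the largest increases rose by 2.57 to 5.31 on the log2 scale. M17 (AT2G41260), a late embryogenesis abundant protein gene, rose from 3.68 ± 0.0635 (SD, n = 3), inside the range of the trp control probe sets, to 9.0 ± 0.199 (adjusted p = 2.92e-10), and the size of its rise is therefore a lower limit. PDC2 (AT5G54960), a pyruvate decarboxylase of fermentation, rose 7.45-fold from 6.47 to 9.37. CYP71B36 (AT3G26320), a cytochrome P450, rose 6.36-fold from 4.93 to 7.60. Among genes known here by locus, AT3G26460 rose by 4.35, AT4G23680 by 3.70, AT3G02480 by 3.54, AT4G34950 by 3.52, AT4G12490 by 3.09, AT4G15680 by 2.77, AT3G15720 by 2.69, AT3G26470 by 2.62 and AT3G15310 by 2.57. Each of these 24 genes had an adjusted p of at most 1.43e-08 in the limma fit. Some probe sets without a single named gene changed as much: 11 rose by at least the smallest increase of this set and 15 fell by at least its smallest decrease, the extremes being 6.25 and -4.48.

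**Figure D2:**
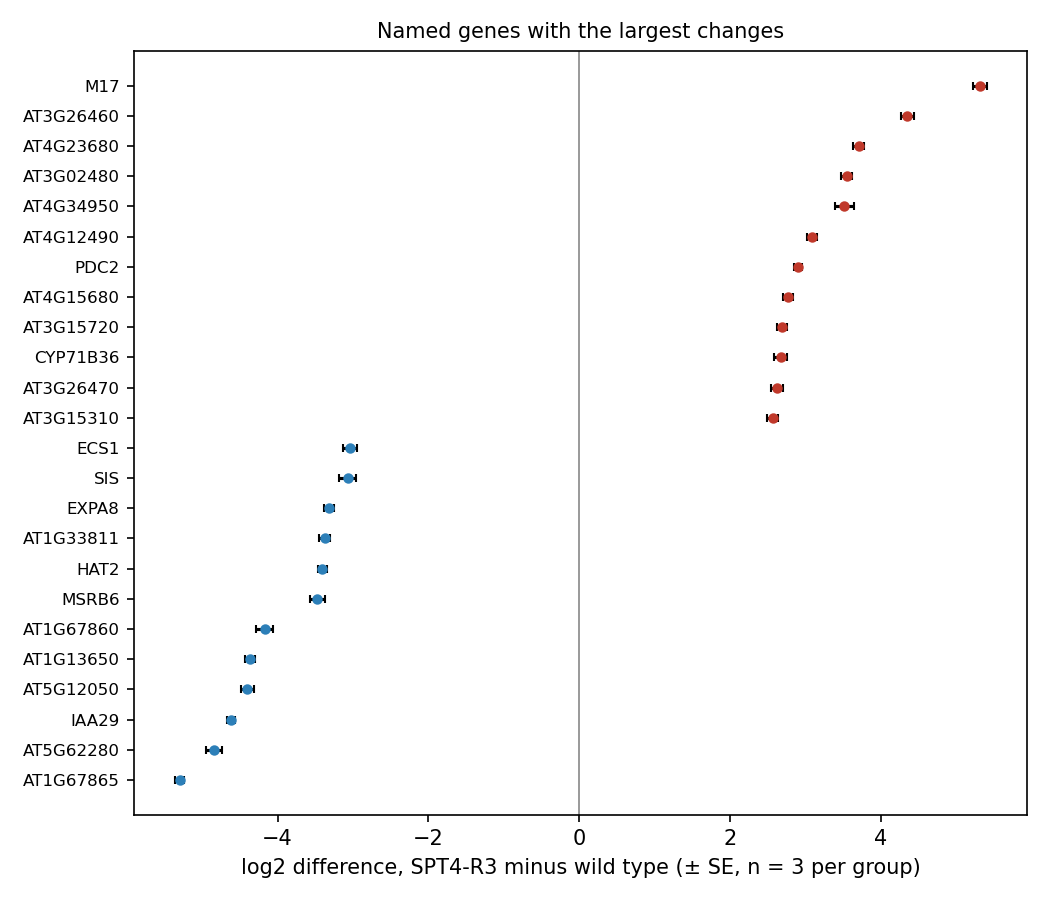
Log2 difference between SPT4-R3 and wild type, with its SE (n = 3 arrays per genotype), for the 12 named genes with the largest rises and the 12 with the largest falls. M17 lies highest at 5.31 and AT1G67865 lowest at -5.30, and the SEs are small beside every difference shown.

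The study asked how auxin-related gene expression responds when SPT4 is targeted by RNA interference. Of 29 Aux/IAA genes in the list fixed beforehand, 7 were measured: IAA18, IAA20, IAA29, IAA30, IAA31, IAA33 and IAA34. The list result holds for these only and cannot stand for the family. Of the 7, 5 fell, none rose and 2 did not pass the test, and adjusted over the list alone 5 fell and 1 rose. IAA20 (4.49 to 4.32) and IAA33 (4.45 to 4.25) were dim. Without the dimmest 30% of probe sets 3 Aux/IAA genes were lower and none higher (camera adjusted p = 9.6e-09). IAA29 fell by 4.62 ± 0.0550 (SE), IAA30 (AT3G62100) by 0.65 ± 0.0588, IAA18 (AT1G51950) by 0.35 ± 0.0963 and IAA20 (AT2G46990) by 0.17 ± 0.0583. The median difference of the list was -0.20 and camera placed it below the other genes with an adjusted p of 2.27e-07 over 5 lists. With an estimated correlation between genes the adjusted p was 0.251, and without IAA29, a choice made after the data were seen, it was 0.484 at the preset correlation. Fewer Aux/IAA genes were called lower when 1 array was left out, 2 without wild-type replicate 3 or SPT4-R3 replicate 2, 3 without wild-type replicate 1 or 2 or SPT4-R3 replicate 1, and 4 without SPT4-R3 replicate 3, with IAA18 and IAA20 among the calls lost. Scaling on bioB, bioC and bioD, which shifts all genes alike, gave 3 higher and 2 lower, with IAA29 and IAA30 still lower. A shift common to all genes cannot move the list relative to the others. Its camera adjusted p of 1.14e-05 under this scaling, at the preset correlation, is therefore no further support.

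Of 25 GH3 and SAUR genes, which are early auxin response genes, 5 were measured; 4 fell and 1 did not pass the test, also when adjusted over the list alone. GH3.5 (AT4G27260), which encodes an enzyme joining auxin to amino acids, fell from 9.0 ± 0.139 (SD, n = 3) to 7.31 ± 0.0723, a 3.22-fold reduction (adjusted p = 6.02e-08). SAUR10 (AT2G18010) fell from 5.33 to 3.71, with SPT4-R3 values of 3.61 to 3.82 inside the 3.46 to 3.84 of the trp control probe sets, so that the size of its fall is a lower limit. GH3.17 (AT1G28130) fell 1.61-fold from 8.92 to 8.23 and GH3.1 (AT2G14960) 1.29-fold from 4.60 to 4.23. The list lay below the other genes by camera (median -0.69, adjusted p = 0.000115), with an adjusted p of 0.170 with an estimated correlation. Scaling on bioB, bioC and bioD gave 3 lower and 1 higher, and GH3.1 then differed by 0.03. Such a common shift cannot move the list relative to the other genes. The camera adjusted p of 7.97e-05 under this scaling, at the preset correlation, is therefore no further support. Of the 21 auxin transport and synthesis genes 3 were measured, YUC2, YUC4 and YUC6, too few for the list test. No transport gene was among them. YUC2 (AT4G13260), a flavin monooxygenase of auxin synthesis, fell by 1.05 ± 0.0790 (SE) and its relative YUC6 (AT5G25620) rose by 0.36 ± 0.0564. YUC4 did not pass the test, with a difference of 0.12 (adjusted p = 0.258 in limma). None of the 20 auxin response factor and receptor genes was analysed here.

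**Figure D3:**
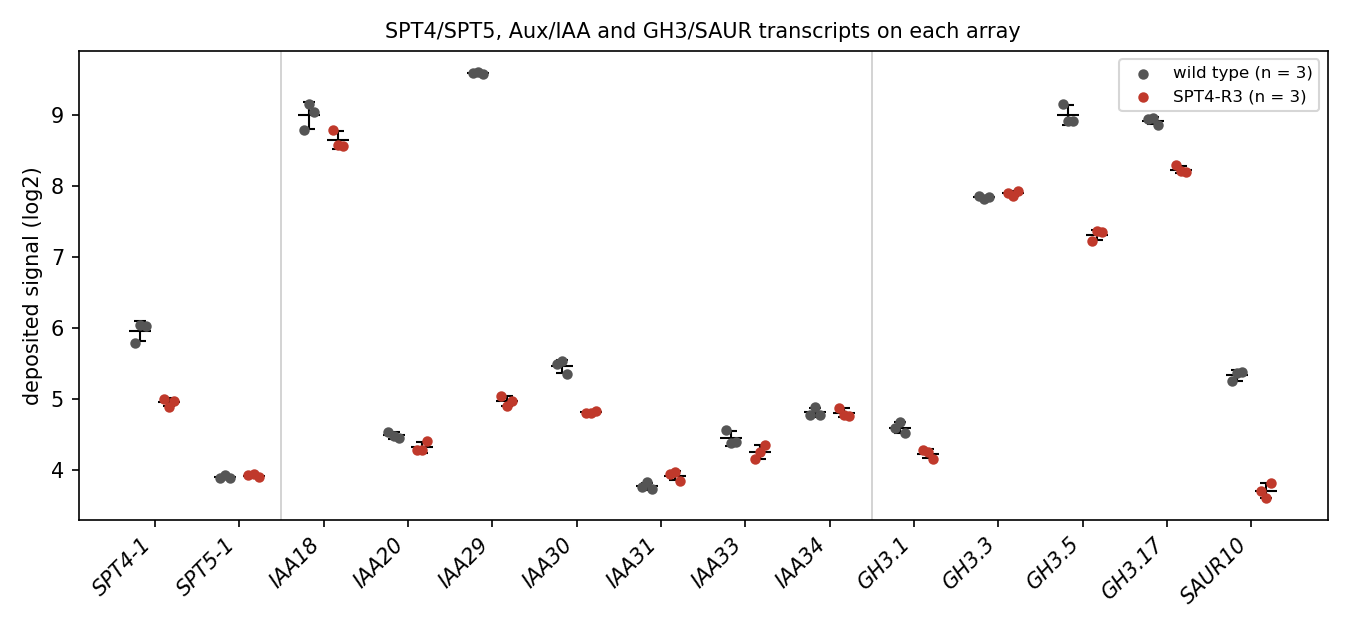
Deposited log2 signal on each array for the measured SPT4 and SPT5 genes (left), Aux/IAA genes (middle) and GH3 and SAUR genes (right), with genotype means and SDs (n = 3 arrays per genotype). IAA29 drops from 9.59 to 4.97 and GH3.5 from 9.0 to 7.31, while GH3.3 lies at 7.84 and 7.90; scaling on bioB, bioC and bioD would raise the SPT4-R3 points by 0.39 on average, which puts the SPT4-R3 means of IAA18, IAA20, IAA33, IAA34 and GH3.1 above wild type.

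A cell wall family and a calmodulin-binding family also held many falls, though only the first passed the test. These families were formed from shared symbol stems after the annotation had been seen, and their members are named after their values were seen. Of 9 xyloglucan endotransglucosylase/hydrolase (XTH) genes, whose enzymes remodel cell walls, 6 fell and none rose (median -0.36, camera adjusted p = 0.0114 over 47 families). In the camera run with an estimated correlation, here -0.0626, the adjusted p of XTH was 0.515. Under the bioB, bioC and bioD scaling, which shifts all genes alike, 4 were lower and 3 higher. Since it cannot move the family relative to the other genes, the camera adjusted p of 0.00104 under it (preset correlation) is no further support. XTH19 (AT4G30290) fell by 1.82 ± 0.0912 (SE), XTH33 (AT1G10550) fell by 1.64 ± 0.0818 and XTH16 (AT3G23730) fell by 0.85 ± 0.0700. The expansin (EXPA) family, also of the cell wall, was mixed, with 4 lower and 1 higher of 10, and did not pass (camera adjusted p = 0.0741). Of 15 IQD genes, which encode calmodulin-binding proteins, 11 fell and 1 rose, but the family did not pass the test (adjusted p = 0.0741). Leaving out wild-type replicate 3 brought the IQD value to 0.0266, and the bioB, bioC and bioD scaling gave 4 higher and 4 lower. IQD22 (AT4G23060) fell by 1.26 ± 0.0753 (SE) and IQD23 (AT5G62070) rose by 0.57 ± 0.0747.

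The measured NRPB genes, named for subunits of RNA polymerase II, were higher in SPT4-R3. They were NRPB6A, NRPB6B, NRPB7, NRPB9A, NRPB9B and NRPB12, and the other subunits were not covered. All 6 measured NRPB genes rose, by 0.19 to 0.65, with NRPB7 (AT5G59180) going from 7.71 ± 0.0529 (SD, n = 3) to 8.36 ± 0.0651 and NRPB9B (AT4G16265) from 6.58 to 7.15. The 6 remained higher under each scaling, while 5 were called when wild-type replicate 1, SPT4-R3 replicate 1 or SPT4-R3 replicate 2 was left out. As a family they did not stand apart from the other genes (camera adjusted p = 0.118). None of the 18 elongation factor and polymerase genes in the list fixed beforehand was analysed here.

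Genes of cold and drought response were divided. Of 4 measured, COR47 (AT1G20440) and LTI30 (AT3G50970), both dehydrins, fell by 2.38 ± 0.0602 (SE) and 0.79 ± 0.0670, while COR15B (AT2G42530) rose by 0.41 ± 0.0618. The list lay below the other genes (median -0.31, camera adjusted p = 0.00390, or 0.593 with an estimated correlation), and adjusted over the list alone 2 rose and 2 fell. COR47 changed by far the most of the 4, and the list was not tested without it. Flavonoid synthesis was also divided, with 2 of 4 higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.885). UGT78D2 (AT5G17050) rose by 0.56 and UGT75C1 (AT4G14090) by 0.45, and DFR (AT5G42800), a reductase on the way to anthocyanins, fell by 0.64 and UF3GT (AT5G54060) by 0.36. Scaling on bioB, bioC and bioD gave 2 higher and 2 lower cold and drought genes, and 2 higher and 1 lower flavonoid genes. This scaling shifts all genes alike and cannot move the cold and drought list relative to the others. Its camera adjusted p of 0.00801 there, at the preset correlation, is therefore no further support.

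The markers of root tissue, which the harvest of aerial parts should leave out, did not pass the test in any of the 4 measured genes, over all probe sets or adjusted over the list alone (camera adjusted p = 0.885). The 2 with the smallest p were EXPA7 (AT1G12560), with a difference of -0.12 ± 0.0777 (SE), and PYK10 (AT3G09260), a root beta-glucosidase, with -0.02 ± 0.0552. PYK10 read 11.8 in both genotypes, above the upper quartiles of the arrays (8.3 to 8.35). The list therefore does not show that root tissue was left out. The other markers were dim, at 4.95 and 4.83 for EXPA7, 5.14 and 5.15 for EXPA18 (AT1G62980) and 4.23 and 4.22 for PRX44 (AT4G26010) in wild type and SPT4-R3, so that small differences in them could be missed. Under the bioB, bioC and bioD scaling all 4 were called higher, with EXPA7 at 0.28 and PYK10 at 0.38.

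Lists with fewer than 4 measured genes were not tested as lists. In light harvesting, LHCB4.2 (AT3G08940) fell by 1.14 ± 0.0513 (SE) and LHCB4.1 (AT5G01530) by 0.51 ± 0.0502. In the cytosolic ribosome, RPL4D (AT5G02870) rose by 0.52, RPL4A (AT3G09630) by 0.31 and RPL28A (AT2G19730) by 0.17. Of the type-A cytokinin response regulators, ARR16 (AT2G40670) rose 5.49-fold from 5.59 ± 0.356 (SD, n = 3) to 8.05 ± 0.0404, whereas ARR15 (AT1G74890) fell 1.75-fold. The gibberellin receptor gene GID1A (AT3G05120) rose by 1.04 and GID1B (AT3G63010) fell by 0.19. In glucosinolate metabolism, BCAT4 (AT3G19710), which acts in methionine chain elongation, fell 4.31-fold, UGT74C1 (AT2G31790) fell by 0.32 and UGT74B1 (AT1G24100) rose by 0.47. BHLH101 (AT5G04150), an iron deficiency transcription factor, fell 2.71-fold. Under the bioB, bioC and bioD scaling GID1B and UGT74C1 turned to 0.20 and 0.073, and LHCB4.1 lost its call at -0.12 (adjusted p = 0.269 in limma).

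The remaining measured list members were few. ROF2 (AT5G48570), a heat-induced immunophilin, rose by 1.46 ± 0.0833 (SE) in the heat shock list. HSP17.6C and HSP22, the other measured genes of that list, were dim and did not pass the test, with differences of 0.04 (adjusted p = 0.691 in limma) and 0.05 (0.495). SAG101 (AT5G14930), of salicylic acid defence, rose by 0.47 and ZAT10 (AT1G27730), a rapidly induced zinc finger gene, fell by 0.42. SNZ (AT2G39250) and SMZ (AT3G54990), related repressors of flowering, moved apart, with differences of -0.94 in SNZ and 0.49 in SMZ, both called. YAB3 (AT4G00180), of leaf polarity, fell by 0.60 and PRL (AT4G02060), of DNA replication, rose by 0.46. PHV and YAB5, measured in the same list as YAB3, and FD, in the flowering list, did not pass the test. PDF1.2 (AT5G44420), of jasmonate response, and GI (AT1G22770), of the circadian clock, did not pass the test, with differences of -0.10 (adjusted p = 0.332) and -0.09 (adjusted p = 0.258). Under the bioB, bioC and bioD scaling ZAT10 and YAB3 lost their calls at -0.023 and -0.21, and PDF1.2 and GI were called higher at 0.29 and 0.31. No gene of the brassinosteroid, ethylene, floral organ, phosphate, seed, shade and light, silencing or xylem lists was analysed here. The calls of RPL28A and GID1B each ended when some single arrays were left out, RPL28A without wild-type replicate 3 (adjusted p = 0.0586), SPT4-R3 replicate 1 (0.0685) or 2 (0.0529), and GID1B without wild-type replicate 1 (0.0531) or 3 (0.0593) or SPT4-R3 replicate 1 (0.0705) or 2 (0.0837).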

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

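The test on hybridisation controls and the splits of the arrays were chosen after the results were seen, and the test on signal level before. The Arabidopsis GAPDH control probe sets, which are not among the probe sets tested, were higher on all 3 SPT4-R3 arrays than on any wild-type array, by 0.53 on the log2 scale, and the scaling on bioB, bioC and bioD would add 0.39 to that. The ubiquitin control probe sets separated the genotypes in the other direction, with a difference of -0.30, which that scaling would turn.

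About 50% of all probe sets were called between the genotypes, 11351 in all. The 6 arrays can be split 10 ways into 3 and 3, too few for a share under 0.05. The genotypes gave 11351 calls, the only split of the 10 (1 of 10) to give that many. The highest of the other splits gave 0 in limma (at most 448 probe sets at an unadjusted p under 0.05). Each of those splits mixes the genotypes, so the genotype difference enters its residual spread and lowers its calls. The splits therefore do not decide on chance. Mean signal explained 0.185% of the variance of the differences, which argues against an average signal-dependent shift left in the deposited values. The array quartiles were already alike, with lower quartiles of 4.41 to 4.44 and upper quartiles of 8.3 to 8.35. A change of scale or background that depended on the signal before normalization could therefore not be seen, and it stays open. Array handling that went with the genotype stays open: the bioB, bioC and bioD controls differed by -0.39, more than their spread, while the hybridisation control cre differed by -0.05 with overlapping values (exact p = 0.7), and handling and genotype cannot be told apart here. The reduction of SPT4 in the line stays open as the biological explanation and was not tested separately. No other RNAi line was among the arrays, so other differences between SPT4-R3 and wild type cannot be told apart from it.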

How the results depend on the processing

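The scalings on array controls and the list without IAA29 were chosen after the data were seen. Counts of called probe sets and genes stayed within 1.5 times of the reported ones under quantile normalization, median centring, removal of the dimmest probe sets, and trend and robust settings. So did the counts of genes without shared-probe identifiers and with the mean of a gene's probe sets. Leaving out any 1 array gave 5326 to 5722 higher and 4633 to 5060 lower probe sets. The test against 0.5 log2 gave 1200 higher and 1222 lower, as its stricter construction implies. The replicate number as a block gave 5663 higher and 5007 lower. Same-numbered arrays did not deviate together (correlations -0.24, -0.13 and -0.06), and 0 of 6 arrays correlated best with their own number. These values show no pairing by number, but so few arrays cannot exclude a weak one. Scaling on bioB, bioC and bioD gave 17406 higher and 1589 lower probe sets and 10450 higher and 798 lower genes. It turned 10 of 64 named genes, to 0.043 for IAA18, 0.23 for IAA20, 0.03 for GH3.1, 0.29 for PDF1.2, 0.31 for GI, 0.033 for UF3GT, 0.20 for GID1B, 0.073 for UGT74C1, 0.28 for EXPA7 and 0.38 for PYK10, ended the calls of LHCB4.1 (-0.12), ZAT10 (-0.023) and YAB3 (-0.21), and brought SPT5-1 past the threshold at 0.41. Scaling on poly-A controls left 2478 lower probe sets and 1263 lower genes and ended the calls of 7 named genes. It changed the sign of 4, none called on either scale, to 0.049 for PDF1.2, 0.063 for GI, 0.033 for EXPA7 and 0.13 for PYK10. The shift is only part of the cause. The spread of the control factors over arrays raised the SE from a median of 0.0632 to 0.104 (bioB, bioC and bioD) and 0.121 (poly-A) for every probe set. In a test added after the data were seen, the mean shift alone ended 5 of the 8 calls lost under bioB, bioC and bioD. LHCB4.1 and YAB3 kept their lower calls, while GID1B counted as kept only because the shift turned it to a higher call. Under poly-A the mean shift alone ended 3 of the 7 calls lost. SPT4-1 stayed lower under every alternative, by 0.61 at the least. In the camera run with an estimated correlation the adjusted p was 0.251 for Aux/IAA and 0.170 for GH3 and SAUR. It was 0.593 for cold and drought and 0.515 for XTH. A larger correlation does not account for GH3 and SAUR, cold and drought or XTH, whose estimates lay below the preset. Without IAA29 the camera adjusted p at the preset correlation was 0.484 for Aux/IAA. By fry, which does not compare a family with other genes, 37 of 47 families passed, IQD (0.000137) and NRPB (0.00117) among them. Leaving out 1 array moved the adjusted p of IQD between 0.0266 and 0.122; the cause was not tested. Trend and robust settings ended the calls of IAA20 (adjusted p = 0.0589) and GID1B (0.0520), and the block those of IAA20 and RPL28A. Without the dimmest 30%, too few genes were left to test GH3 and SAUR, root markers or XTH, and SPT5-1 was removed. A transform for linear signals was not run because the values are log2. Signals near the trp control are limited by background.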

Other observations

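The families and the order of adjacent genes were examined after the results were seen, and the test without shared-probe identifiers was set before. Among families formed from symbol stems, several leaned one way without passing the test over 47 families, and examples are given here. Of 47 UDP-glycosyltransferase (UGT) genes 20 rose and 6 fell (camera adjusted p = 0.154), with UGT71B1 up by 1.4 ± 0.0533 (SE, n = 3 per genotype) and UGT71C4 down by 0.83 ± 0.0581. Of 26 genes with CYP symbols, which are cytochrome P450 genes apart from the cyclophilin genes CYP71 and CYP59, 11 rose, CYP71 among them, and 3 fell (adjusted p = 0.0741), and the cytochrome P450 gene CYP71B23 rose by 1.17 ± 0.0556. Most of the 26 were CYP71B genes, several of them at neighbouring loci, so the lean need not hold for cytochrome P450 genes at large. The ubiquitin-specific protease (UBP) genes gave 6 higher and 1 lower of 12 (adjusted p = 0.0741) and the CLE peptide genes 4 higher and 1 lower of 6 (adjusted p = 0.118), CLE44 rising by 1.07 ± 0.0727. Trichome birefringence-like (TBL) genes, several of which act in cell wall acetylation, gave 8 lower and 2 higher of 22 (adjusted p = 0.0741).

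Transcripts of the organelles were measured too. Of the plastid-encoded ribosomal protein genes, 5 of 7 of the large subunit and 4 of 8 of the small subunit fell and none rose, without passing as families (camera adjusted p = 0.332 and 0.560). The plastid gene rpl36 fell from 12.46 ± 0.107 (SD, n = 3) to 11.63 ± 0.199. Of 8 nad genes, which encode subunits of a respiratory complex, 2 fell, with differences of -1.22 ± 0.107 (SE) for nad2 and -0.64 ± 0.0653 for nad7, and none rose. These transcripts were compared on the deposited scale, and the bioB, bioC and bioD scaling would add 0.39 to each difference.

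Adjacent genes changed alike to a small extent over all genes, but not beyond chance among genes with changes under 1 on the log2 scale. Of the 24 genes with the largest changes, AT1G67860 and AT1G67865 are adjacent and fell by 4.17 and fell by 5.30, and AT3G26460 and AT3G26470 are adjacent and rose by 4.35 and 2.62. Over 5227 adjacent pairs, the log2 differences correlated at r = 0.0886 (rho = 0.0447), above the highest of 1000 shuffled orders, 0.0425, which argues against a chance order; genes are not independent replicates. The r was 0.0454 (rho = 0.0315) for genes 2 apart, -0.000404 (rho = 0.0142) for genes 5 apart and 0.0137 (rho = 0.0248) for genes 10 apart. For adjacent pairs without those 24 genes r was 0.0465 and rho 0.0407, and without the 547 genes changed by at least 1 they were 0.0160 and 0.0239, with r below the highest shuffled value of 0.0410 (permutation p = 0.140). The last choice selects on the differences that are correlated, which by itself can lower r, so whether the likeness extends beyond genes with large changes stays open. Probe sets shared by similar genes may still play a part: without identifiers that mark shared probes r was 0.0899, but probes not marked as shared were not checked.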
